A study of Homo sapiens with 15 samples.

How the data were processed

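Gene expression was measured by RNA sequencing of polyA RNA in 15 libraries, 1 stem library and 4 NP-like libraries for each of the lines ESC3, ESC9 and IMR90-iPSC. Per the labels, RNA was taken with Trizol and libraries were made with an Illumina TruSeq kit. Per the submitters' processing notes, HISAT2, SAMtools 0.1.18, Cufflinks and HTSeq were used with the genome build GRCh38; their roles, the other versions and the annotation release are not given in the sources used here. The authors deposited 1 table of FPKM (fragments per kilobase of gene, scaled to the mapped fragments of the library) with the gene tracking columns of Cufflinks, and log2(FPKM+1) was computed from the deposited FPKM. The table gives no counts. It had 58118 lines for 58024 gene identifiers. For 93 identifiers there were several lines, which repeated a single value in 14 libraries, and in 78 of them NP_ESC3 replicate 1 differed between lines. The line that spans the longest region was kept for each identifier. Of the identifiers, 57420 matched GENCODE release 29, and 55275 of these (96.3%) had the same start and end there, so GENCODE gave the gene type. Every value column was mapped to a sample, with 0 left over. The 37 mitochondrial genes were listed at 0 in every library, so a listed 0 may stand for an estimate that was not made, and no fold is given against libraries that are all listed at 0. A change over the 3 lines can include 1 stem library listed at 0.

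The FPKM of a library summed to 352217 to 391106, and the 10 highest genes took 5.1% to 7.55% of the sum. The highest gene was TMSB4XP6, a pseudogene of thymosin beta 4, at 1.08% to 2.48%. It can share reads with its parent gene, so its value may not be its own. Depth is not given in the table. It was estimated from olfactory receptor genes of 900 to 1000 bp, whose small values step in whole fragments within a tolerance of 0.03. Of 230 such genes, only the 5 to 16 per library taken as 1 or 2 fragments set the estimate. It was 34100000 to 44300000 fragments per library (median 38300000). At that depth 1 FPKM over 1 kilobase is about 38.3 fragments, so values well under 1 FPKM rest on few fragments, and the estimate covers counting only. In a check for mixed-up samples, 12 of 12 NP-like libraries were closest to the stem library of their own line.

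Lists, tests, thresholds, alternatives and the rule for named genes were chosen before the data were examined, except where the text says otherwise. Tests were run in R 4.3.3 with limma 3.58.1 (moderated fit with a trend, Benjamini-Hochberg adjusted p), with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 for tables and plots. A gene was called at an adjusted p under 0.05 with a change of at least 2-fold on log2(FPKM+1), and p-values are two-sided. NP-like cells were compared with stem cells on 6 values, the 3 stem libraries and the mean log2 value of the 4 NP-like libraries of each line, with the line as a block (2 residual and 3.47 prior degrees of freedom). Genes needed 1 FPKM in at least 3 of 15 libraries, which left 16768. A gene of stem cells alone needed all 3 stem libraries, and a gene of NP-like cells alone any 3 of 12. The tested genes therefore lean toward those of NP-like cells. Changes within a line, and limma's F test of whether they differ among lines with a range of at least 1 in log2 change, came from a fit of 6 groups to 15 libraries (9 residual and 3.03 prior degrees of freedom), in which the lone stem library of a line is assumed to vary like the other groups. NP-like groups were compared in a fit of 12 libraries (9 residual and 3.2 prior degrees of freedom), with genes of 1 FPKM in at least 4 of 12, which left 15694. The agreement of the lines was described by the correlation of log2 changes across genes.

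There were 29 gene lists: pluripotency, notochord, nucleus pulposus, cartilage matrix, fibrous matrix, tendon and annulus, hypertrophic and bone, paraxial mesoderm and sclerotome, lateral mesoderm and heart, smooth muscle, skeletal muscle, neural, neural crest and Schwann, endoderm and liver, endothelium, epithelium, trophoblast, blood, proliferation, TGF-beta, BMP, Hedgehog, Wnt, hypoxia and glycolysis, matrix turnover and cytokines, interferon response, HOX, imprinted and mitochondrial mRNA. Some genes are in more than 1 list. Members under the filter were not tested and are not in the counts of tested members. For example, 15 of 23 cartilage matrix and 8 of 13 notochord members were tested in NP-like versus stem cells. The same holds for 9 of 15 members for paraxial mesoderm and sclerotome and 7 of 14 for endoderm and liver. The 23 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, which is reported beside each call. With the preset correlation, the degrees of freedom of the test follow the number of genes. With an estimated one they are the residual degrees of freedom of the fit. These were 2 for NP-like versus stem cells, where a list could hardly pass, and 9 between NP-like groups. Camera asks whether a list moves more than the other genes. Named genes were the 12 highest and 12 lowest called log2 changes in NP-like versus stem cells that move the same way in the 3 lines, the 6 highest and 6 lowest called differences per contrast of NP-like groups, and the 10 called interaction genes with the largest range. Genes with no symbol or a clone-based name, genes of chromosome Y, XIST and TSIX were left out of the ranking. Other genes of the X chromosome stayed in it. Some genes that this rule or the lists select are not reported here. Members of the lists may also be named, and 17 genes of the notochord, disc and pluripotent state were always reported. Relations between list means across libraries used values relative to the mean of the line, with permutation within lines. That family was planned with 4 relations and widened to 8 after the data were seen, and the tests that take the replicate number into account were added then too. The search for a library far from the others of its group was also widened after the data were seen, to cover every gene that the rule names, and the rule for weighing depth was changed to ask for the depth-adjusted relation as well.

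The procedure was tested on simulated data with 200 changed genes. With a log2 change of 1, 52.2% of the changed genes were recovered in NP-like versus stem cells and 37.3% between NP-like groups, and with a change of 2, 100% and 98.5%. A log2 change of 1 equals the 2-fold minimum, so estimates that fell under it were not called. False calls were 13 of 16568 and 1 of 15494 genes, and camera called the 1 raised list of 23. The simulated genes varied independently of each other, so the camera result does not cover lists whose genes vary together. For changes within a line and for the interaction at a log2 change of 2, 95.5% and 89.6% were recovered. The interaction was scored there on the adjusted p alone, without the minimum range. The simulated stem library varied like the NP-like replicates, so these values do not check that assumption. Simulated values also had no floor at 0, unlike real values of low genes. The alternatives were a pseudocount of 0.1, no filter or a filter of 5 FPKM, median-ratio or TPM scaling, limma without a trend or with robust variance, no fold minimum, single libraries or no block for the line, a random block, the replicate number as a block, only the 8 libraries of a pair, leaving out each of the 12 NP-like libraries in turn and, for NP-like versus stem cells, each line. Stem libraries were left out only with their line. Protein-coding genes alone, leaving out the 3 libraries with the highest fibrous list means, and leaving out single libraries for the list tests and the agreement were added after the data were seen. Left out were transcript isoforms, which a gene table does not resolve, and comparisons with other data on discs.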

Results

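PolyA RNA was sequenced from 15 libraries of 3 human pluripotent lines. ESC3 and ESC9 are embryonic stem cell lines, and IMR90-iPSC is an induced pluripotent stem cell line. Each line gave 1 library of undifferentiated stem cells (passages 15 to 20) and 4 libraries of nucleus pulposus-like cells, called NP-like cells and named NP_ESC3, NP_ESC9 and NP_IMR90. The nucleus pulposus is the gel-like core of the intervertebral disc, which descends from the embryonic notochord. The differentiation used Activin A at 10 ng/mL for 2 days, then Activin A, FGF2 at 10 ng/mL, Noggin at 50 ng/mL, CHIR at 3 µM and AGN193109 at 10 µM for 3 days, then TGF-β3 at 10 ng/mL with ascorbate phosphate and proline for 15 days. CHIR activates Wnt signalling, Noggin binds BMPs and AGN193109 blocks retinoic acid receptors. Each library had 14213 to 15276 genes at 1 FPKM or more, and its depth was estimated at 34100000 to 44300000 fragments, so that 1 FPKM stood for about 38.3 fragments per kilobase in the median library. The labels do not say whether the 4 libraries of a line came from separate differentiations, so the p-values measure the spread between these samples. Pearson correlations of log2(FPKM+1) across genes were 0.963 to 0.991 between NP-like libraries of a line, 0.898 to 0.958 between NP-like libraries of different lines, and 0.81 to 0.851 between NP-like and stem libraries.

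The first comparison asked which genes differ between stem cells and the NP-like cells made from them, with the line as the unit. Transcripts that mark the pluripotent state were among those lower in NP-like cells, and transcripts for collagens, contractile proteins and neural proteins among those higher. COL3A1 (ENSG00000168542.13, chromosome 2, 188974320 to 189012746 of GRCh38), which encodes the chain of type III collagen, rose from 0.175 ± 0.1604 to 418 ± 424 FPKM (mean ± SD, n = 3 lines), a log2 change of 7.73 ± 0.44 (SE, limma adjusted p = 0.000393). POU5F1 (ENSG00000204531.16, chromosome 6, 31164337 to 31180731), a transcription factor required for pluripotency, went from 383 ± 5.41 to 1.34 ± 2.16 FPKM and fell by 7.96 ± 0.32 on the log2 scale (limma adjusted p = 0.000225), though POU5F1 has pseudogenes that can share its reads. NP_ESC3 replicate 1 stood apart at 12.4 FPKM of POU5F1, and without it the NP-like mean was 0.39 FPKM and the log2 change -8.2. Of 16768 genes tested, 1903 were higher and 1174 lower in NP-like cells, and 3074 of these 3077 moved the same way in the 3 lines. A call over 3 lines needs changes that are alike, so that agreement follows largely from the call itself.

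The largest called increases are given as the log2 change ± SE over 3 lines. IGF2, an imprinted fetal growth factor, rose by 6.99 ± 0.26, to 412 ± 259.7 FPKM. The orphan nuclear receptors NR2F1 and NR2F2 rose by 6.41 ± 0.24 and 5.33 ± 0.14. ZIC1, a zinc finger factor of neural and somite development, rose by 6.35 ± 0.13 to 123 ± 16.95 FPKM. WLS, the carrier that brings Wnt proteins to the cell surface, rose by 6.19 ± 0.24, and SEMA3C, a secreted guidance molecule, by 5.56 ± 0.33. LUM, the collagen-binding proteoglycan lumican, rose by 6.01 ± 0.48, and TNC, the matrix glycoprotein tenascin C, by 5.04 ± 0.19. ANXA1, a calcium-dependent phospholipid-binding protein, rose by 5.29 ± 0.30. The contractile genes ACTA2 and TAGLN rose by 5.12 ± 0.38 and 4.95 ± 0.23, TAGLN reaching 887 ± 273 FPKM.

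The largest called decreases included genes of the pluripotent and epithelial state. MIR302B, annotated as an antisense transcript over the miR-302 cluster of stem cell microRNAs, fell by 9.02 ± 0.49 from 879 ± 302 FPKM. TDGF1, a Nodal co-receptor, went from 237 to 0.364 FPKM, and to 0.118 FPKM without NP_ESC3 replicate 1 (3.234 FPKM). That library also had the highest MIR302B (13.6 FPKM) and ESRG (6.23 FPKM) of the 12 NP-like libraries. The long non-coding RNAs ESRG and LINC00678 fell by 6.82 ± 0.30 and 5.71 ± 0.13. ZSCAN10, a zinc finger factor of stem cells, fell by 5.83 ± 0.13, and L1TD1, an RNA-binding protein of stem cells, fell by 5.30 ± 0.21. CDH1, the epithelial cadherin, went from 108 ± 8.47 to 1.697 ± 1.42 FPKM. CLDN7, a tight junction protein, fell by 5.17 ± 0.29, and ESRP1, an epithelial splicing regulator, fell by 5.05 ± 0.18. EPHA1, an ephrin receptor, fell by 5.21 ± 0.12. LECT1, which encodes the cartilage glycoprotein chondromodulin, also fell by 5.29 ± 0.22.

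**Figure D1:**
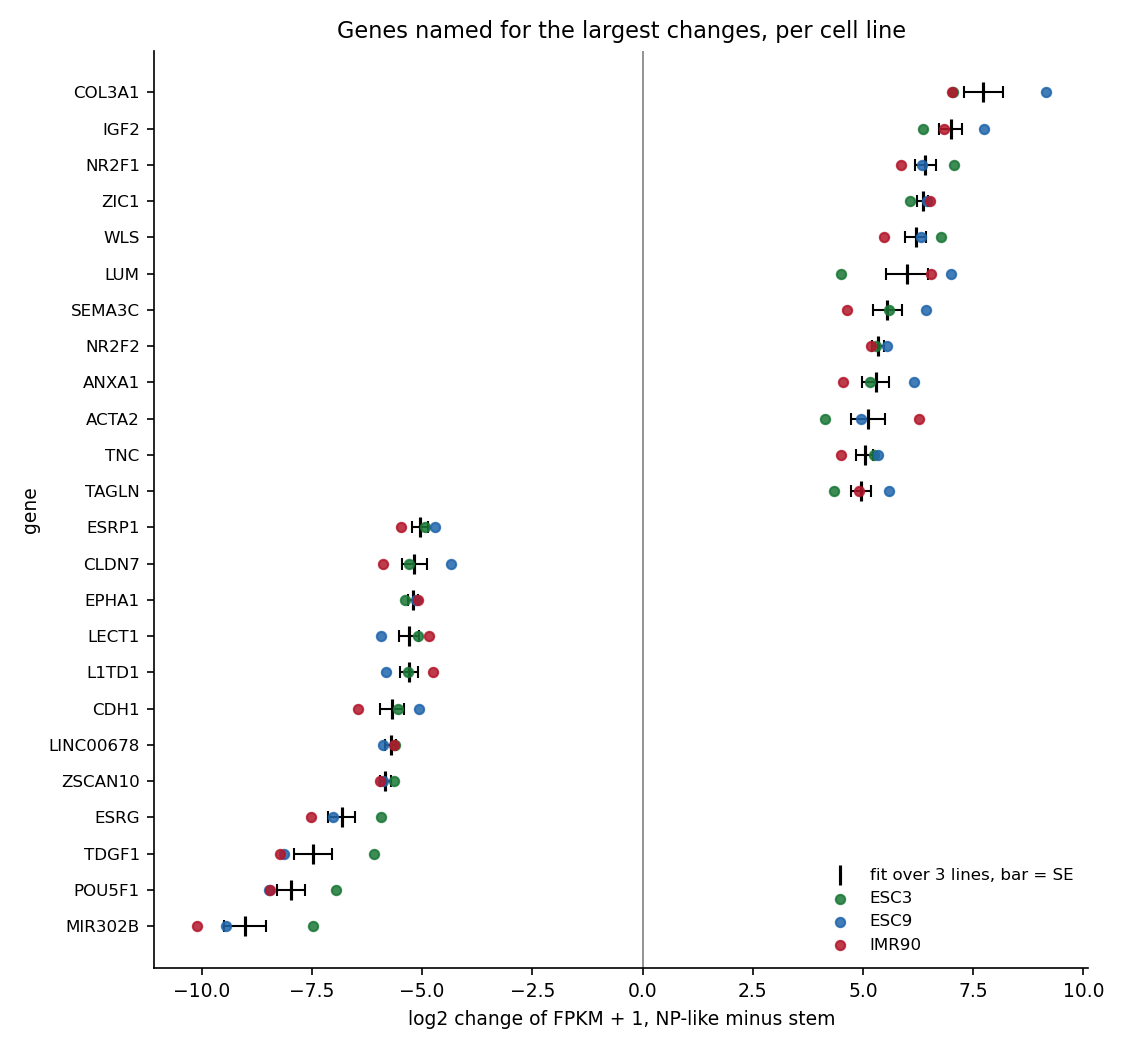
Log2 change of FPKM+1 from stem to NP-like cells (x axis) for 24 genes (y axis). Colored points give each line's change and black points give the fit over 3 lines ± SE. The 12 higher genes run from 4.95 to 7.73 and the 12 lower genes from -5.05 to -9.02, with the 3 lines on the same side of 0, which the rule for these genes required.

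Pluripotency genes fell as a group: 0 of 19 tested members rose, 16 fell and 3 did not pass (adjusted p = 1.52e-12, adjusted p = 0.339 with an estimated correlation). NP_ESC3 replicate 1 had the highest pluripotency list mean of the NP-like libraries, 3.12 log2(FPKM+1), against 2.44 to 2.61 in the other NP_ESC3 libraries. LIN28A, an RNA-binding repressor of let-7 microRNAs, fell by 4.65 ± 0.17, and DNMT3B, a DNA methyltransferase, fell by 4.23 ± 0.09. SOX2, a factor shared with neural progenitors, went from 115.4 ± 19.7 to 50.01 ± 11.03 FPKM. NANOG (ENSG00000111704.10, chromosome 12, 7787794 to 7799141), a pluripotency homeobox gene, fell by 2.93 ± 0.50 over the lines (limma adjusted p = 0.00728), but its NP-like means were 0.276, 0.021 and 10.02 FPKM in the ESC3, ESC9 and IMR90 lines. NANOG did not pass without the filter on low values (limma adjusted p = 0.0532), and its retrocopy NANOGP8 can share its reads. LIN28B and LEFTY2 did not pass, with log2 changes of -0.996 and 0.28. In the epithelium list, 1 of 8 tested members rose, 5 fell and 2 did not pass (adjusted p = 0.000191, adjusted p = 0.412 with an estimated correlation), and 8 passed when adjusted over the list alone. EPCAM, an epithelial adhesion molecule, fell by 5.003 ± 0.22, and GRHL2, an epithelial transcription factor, fell by 2.44 ± 0.20. The member that rose was KRT17, a keratin, by 1.37 ± 0.30, and it did not pass without the ESC3 line (1.05, limma adjusted p = 0.0768).

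Matrix genes rose. In the fibrous matrix list, 22 of 24 tested members rose, 0 fell and 2 did not pass (adjusted p = 2.01e-09, adjusted p = 0.412 with an estimated correlation). FN1, which encodes fibronectin, went from 15.6 ± 4.17 to 532 ± 348 FPKM, a log2 change of 4.67 ± 0.19. COL1A1 and COL1A2, the chains of type I collagen, rose by 2.34 ± 0.24 and 3.11 ± 0.22, and DCN, the proteoglycan decorin, by 4.78 ± 0.66. The members that did not pass were COL14A1 (-0.32) and THBS2 (0.23). In the cartilage matrix list of 23 genes, 10 of 15 tested members rose, 1 fell and 4 did not pass (adjusted p = 0.0121, adjusted p = 0.412 with an estimated correlation). COL2A1 (ENSG00000139219.17, chromosome 12, 47972965 to 48004486), the main collagen of cartilage and of the nucleus pulposus, rose by 4.18 ± 0.23, from 7.95 ± 4.84 to 149 ± 18.2 FPKM (limma adjusted p = 0.000378). COL11A1, a minor cartilage collagen, rose by 3.52 ± 0.14, HAPLN1, which links aggrecan to hyaluronan, by 2.61 ± 0.35, and SOX6, a cartilage transcription factor, by 2.15 ± 0.17. ACAN, the proteoglycan aggrecan, was under the filter, at 0.689 ± 0.173 FPKM in stem cells and 0.662 ± 0.136 FPKM in NP-like cells (n = 3 lines).

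SOX9, the master regulator of cartilage, had a log2 change of 1.01 ± 0.19 (limma adjusted p = 0.0109), close to the 2-fold minimum. SOX9 did not pass without replicate 3 (0.97) or 4 (0.98) of NP_ESC3, replicate 1 (0.99), 3 (0.999) or 4 (1.00, just under the minimum) of NP_ESC9, replicate 3 (0.97) or 4 (0.98) of NP_IMR90, the ESC3 line (1.03, limma adjusted p = 0.0527) or the IMR90 line (0.78). It also did not pass with median-ratio scaling (0.93) or without the filter on low values (limma adjusted p = 0.054).

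Markers of the notochord and the nucleus pulposus moved in both directions. In the nucleus pulposus list, 9 of 23 tested members rose, 2 fell and 12 did not pass (adjusted p = 0.154, adjusted p = 0.412 with an estimated correlation). VIM, the intermediate filament vimentin, went from 67.3 ± 51 to 1592 ± 308 FPKM, a log2 change of 4.83 ± 0.35. CDH2, the neural cadherin, rose by 2.63 ± 0.17, A2M, a protease inhibitor, by 3.91 ± 0.25, and CA3, a carbonic anhydrase, by 3.01 ± 0.24. CD24, a surface glycoprotein, fell by 2.62 ± 0.14 from 931 ± 29.1 FPKM, and ITGA6, a laminin receptor subunit, fell by 1.59 ± 0.14. CD24 has paralogous copies that can share its reads. In the notochord list of 13 genes, 3 of 8 tested members rose, 1 fell and 4 did not pass (adjusted p = 0.544, adjusted p = 0.701 with an estimated correlation). FOXJ1, a regulator of motile cilia, rose by 1.56 ± 0.25, and NOG, the BMP antagonist noggin, by 2.48 ± 0.21.

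The notochord transcription factors were low or under the filter. T, the gene brachyury, averaged 0.0913 FPKM in stem cells and 0.131 ± 0.177 FPKM in NP-like cells (SD, n = 3 lines). FOXA2 averaged 0.155 ± 0.205 FPKM, the morphogen SHH 0.336 ± 0.353 FPKM and FOXF1 0.345 ± 0.3496 FPKM in NP-like cells. PAX1, a sclerotome factor, was at 0.04 FPKM in NP_IMR90 replicate 4 and lower in every other library. NOTO, a notochord homeobox gene, was listed at 0 in every NP-like library except NP_IMR90 replicate 1, at 0.009 FPKM. The keratins KRT8, KRT18 and KRT19 did not pass, with log2 changes of 0.26 ± 0.26, -0.46 ± 0.27 and -0.87 ± 0.69 and limma adjusted p of 0.448, 0.215 and 0.339. KRT8 moved to 0.13 without NP_ESC9 replicate 2 and to 0.16 without NP_IMR90 replicate 2, and it turned to -0.105 without the ESC9 line, as KRT19 did to 0.19 without the IMR90 line. KRT8 and KRT18 have many pseudogenes that can share their reads. CA12, a carbonic anhydrase, had a log2 change of -0.36 ± 0.16 (limma adjusted p = 0.114).

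Genes of the nervous system and of contractile cells rose too. In the neural list, 13 of 15 tested members rose, 0 fell and 2 did not pass (adjusted p = 9.29e-06, adjusted p = 0.412 with an estimated correlation). PAX6, a regulator of neural progenitors, went from 0.628 ± 0.537 to 47.5 ± 40.9 FPKM, a log2 change of 4.60 ± 0.35. STMN2 and GAP43, proteins of growing axons, rose by 3.83 ± 0.30 and 3.59 ± 0.11, and TUBB3, a neuronal tubulin, by 2.30 ± 0.13. NEUROD1, listed at 0 in 2 of the 3 stem libraries, and SYT1, with a log2 change of -0.19, did not pass. In the neural crest and Schwann list, 5 of 9 tested members rose, 1 fell and 3 did not pass (adjusted p = 0.243, adjusted p = 0.701 with an estimated correlation). SOX10, a neural crest factor, rose by 1.72 ± 0.17, and S100B by 2.37 ± 0.19. In the smooth muscle list, 9 of 12 tested members rose, 0 fell and 3 did not pass (adjusted p = 0.000115, adjusted p = 0.412 with an estimated correlation). ACTG2, a smooth muscle actin, rose by 3.89 ± 0.41, and CALD1, the actin-binding protein caldesmon, by 2.13 ± 0.12.

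In the list for paraxial mesoderm and sclerotome, the origin of vertebrae and trunk muscle, 6 of 9 tested members rose, 1 fell and 2 did not pass (adjusted p = 0.0837, adjusted p = 0.534 with an estimated correlation). PAX3 and TWIST1, factors of somite and mesenchyme, rose by 4.10 ± 0.24 and 3.77 ± 0.43, while TCF15 fell by 1.51 ± 0.18. In the endoderm and liver list, 2 of 7 tested members rose, 0 fell and 5 did not pass (adjusted p = 0.169, adjusted p = 0.681 with an estimated correlation), and 1 passed when adjusted over the list alone. GATA6, an endoderm and heart factor, rose by 1.51 ± 0.35 but did not pass without the ESC3 line (1.45, limma adjusted p = 0.0912) or the ESC9 line (1.09, limma adjusted p = 0.0709). In the endothelium list, 1 of 5 tested members rose, 1 fell and 3 did not pass (adjusted p = 0.359, adjusted p = 0.538 with an estimated correlation). CLDN5, a tight junction protein, rose by 2.58 ± 0.25, and KDR, a VEGF receptor, fell by 2.27 ± 0.41.

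In the lateral mesoderm and heart list, 3 of 8 tested members rose, 0 fell and 5 did not pass (adjusted p = 0.0431, adjusted p = 0.517 with an estimated correlation). The list did not pass without NP_ESC3 replicate 1 (adjusted p = 0.053), 2 (0.0714), 3 (0.0661) or 4 (0.0611), NP_ESC9 replicate 2 (0.0551) or NP_IMR90 replicate 2 (0.0676). HAND2, a factor of limb and heart mesoderm, was listed at 0 in the 3 stem libraries and reached 15.9 and 22.4 FPKM in NP_ESC9 replicates 1 and 2 against 3.02 and 4.54 in replicates 3 and 4. MYL7, an atrial myosin light chain, rose by 2.75 ± 0.46.

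Some lists had fewer than 5 tested members and no set test. In the hypertrophic and bone list, 2 of 4 tested members rose and 1 fell: ALPL, alkaline phosphatase, fell by 2.50 ± 0.26. In the skeletal muscle list, PAX7, a satellite cell factor, and 1 further member of 4 tested rose, PAX7 by 2.13 ± 0.26. THBS4 alone changed among 4 tested tendon and annulus genes, and fell by 1.77 ± 0.25. HAND1, the member called among 4 tested trophoblast genes, was listed at 0 in the 3 stem libraries, and it did not pass without the ESC3 line (limma adjusted p = 0.111) or the ESC9 line (limma adjusted p = 0.108). HBE1, an embryonic globin and the 1 tested blood gene, rose by 1.30 ± 0.23, but not without the ESC3 line (limma adjusted p = 0.054). The 13 mitochondrial mRNAs were listed at 0 in every library, so no member was tested.

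Genes of several signalling pathways rose. In the TGF-beta list, 15 of 20 tested members rose, 0 fell and 5 did not pass (adjusted p = 4.15e-06, adjusted p = 0.412 with an estimated correlation). TGFB2, a TGF-beta ligand, rose by 4.17 ± 0.23, TGFBI, a TGF-beta-induced matrix protein, by 3.35 ± 0.27, and CDKN2B, a cell cycle inhibitor, by 4.57 ± 0.38. In the BMP list, 12 of 14 tested members rose, 0 fell and 2 did not pass (adjusted p = 5.50e-06, adjusted p = 0.412 with an estimated correlation). The BMP-responsive homeobox genes MSX1 and MSX2 rose by 4.79 ± 0.30 and 4.36 ± 0.28, and the BMP antagonist GREM1 by 4.30 ± 0.24. In the Wnt list, 12 of 19 tested members rose, 2 fell and 5 did not pass (adjusted p = 0.000191, adjusted p = 0.412 with an estimated correlation), and 15 passed when adjusted over the list alone. AXIN2, a Wnt feedback gene, went from 10.96 ± 1.84 to 41.6 ± 1.19 FPKM. LEF1, a Wnt effector, rose by 3.26 ± 0.19, and the Wnt inhibitor DKK1 by 3.72 ± 0.23, while SFRP1, another inhibitor, fell by 3.83 ± 0.14. In the Hedgehog list, 4 of 8 tested members rose, 1 fell and 3 did not pass (adjusted p = 0.0431, adjusted p = 0.412 with an estimated correlation). GLI1, a target gene of the pathway, fell by 1.78 ± 0.24, while the co-receptors BOC and CDON rose by 2.86 ± 0.16 and 2.18 ± 0.13.

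Proliferation genes were lower as a group, though few passed singly: 0 of 23 tested members rose, 3 fell and 20 did not pass (adjusted p = 0.00234, adjusted p = 0.538 with an estimated correlation). The list mean went from 5.77 log2(FPKM+1) in stem cells to 4.94 to 5.38 in NP-like libraries of ESC3, and from 5.69 to 4.88 to 5.60 in those of ESC9. In IMR90-iPSC it hardly moved, at 5.89 in the stem library and 5.62 to 5.91 in NP_IMR90. BUB1, a mitotic checkpoint kinase, fell by 1.48 ± 0.14, MCM3, a replication helicase subunit, fell by 1.21 ± 0.10, and the proliferation marker MKI67 did not pass (-0.12 ± 0.19, limma adjusted p = 0.632). In the hypoxia and glycolysis list, 2 of 16 tested members rose, 6 fell and 8 did not pass (adjusted p = 0.0431, adjusted p = 0.412 with an estimated correlation). The glucose transporter SLC2A3 fell by 1.58 ± 0.10 and hexokinase HK2 fell by 1.16 ± 0.11. This list did not pass without NP_ESC3 replicate 4 (adjusted p = 0.0562) or NP_IMR90 replicate 3 (0.0529), or with median-ratio scaling (0.0533). In the list for matrix turnover and cytokines, 4 of 9 tested members rose, 0 fell and 5 did not pass (adjusted p = 0.0431, adjusted p = 0.412 with an estimated correlation). CCL2, a chemokine, rose by 4.61 ± 0.45, TIMP3, a metalloproteinase inhibitor, by 3.33 ± 0.18, and MMP2, a gelatinase, by 2.50 ± 0.11. That call was lost without NP_ESC9 replicate 2 (adjusted p = 0.0513) or NP_IMR90 replicate 2 (0.0616).

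HOX genes, which set position along the body axis, were listed at 0 or close to it in stem cells, with a highest value of 0.069 FPKM in any stem library. In NP-like cells 30 of 35 tested members rose, 0 fell and 5 did not pass (adjusted p = 1.67e-07, adjusted p = 0.533 with an estimated correlation). HOXB2 reached 27.7 ± 5.22 FPKM and HOXB3 15.6 ± 9.91 FPKM (n = 3 lines), log2 changes of 4.77 ± 0.16 and 3.81 ± 0.36. Among imprinted genes, 6 of 13 tested members rose, 1 fell and 6 did not pass (adjusted p = 0.0205, adjusted p = 0.412 with an estimated correlation). PLAGL1, a zinc finger growth regulator, rose by 4.38 ± 0.24, PEG10, a retrotransposon-derived gene, by 2.17 ± 0.19, and SNRPN, a splicing protein gene, fell by 1.97 ± 0.14. In the interferon response list, 2 of 12 tested members rose, 0 fell and 10 did not pass (adjusted p = 0.0698, adjusted p = 0.676 with an estimated correlation). The members that rose were IFI6, by 1.88 ± 0.33, and IFI44L, by 1.30 ± 0.32. IFI44L did not pass without the ESC9 line (1.08, limma adjusted p = 0.106) or the IMR90 line (1.06, limma adjusted p = 0.0762).

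Across the 23 lists with a set test, 16 were called with the preset correlation of 0.01 and 0 with an estimated correlation. The test with an estimated correlation had 2 degrees of freedom here, so a list could hardly pass it. Except where a second count is given, the number of members called was the same when adjusted over the list alone. The median, the mean and the set test had the same sign in each list. With 15 libraries as single values, the Hedgehog (adjusted p = 0.0706), hypoxia and glycolysis (0.0932), matrix turnover (0.114) and lateral mesoderm (0.155) lists did not pass. With protein-coding genes alone, a setting chosen after seeing the data, the Hedgehog (0.0572), matrix turnover (0.0572) and lateral mesoderm (0.0636) lists did not pass. Without NP_ESC9 replicates 1 and 2 and NP_IMR90 replicate 2, also chosen after seeing the data, the matrix turnover (0.0757) and lateral mesoderm (0.102) lists did not pass. Without the filter on low values, GATA6 (limma adjusted p = 0.0905), KDR (0.0577), HAND2 (0.0565), MYL7 (0.0525), HAND1 (0.112), IFI6 (0.0554), IFI44L (0.0948) and KRT17 (0.0786) did not pass.

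**Figure D2:**
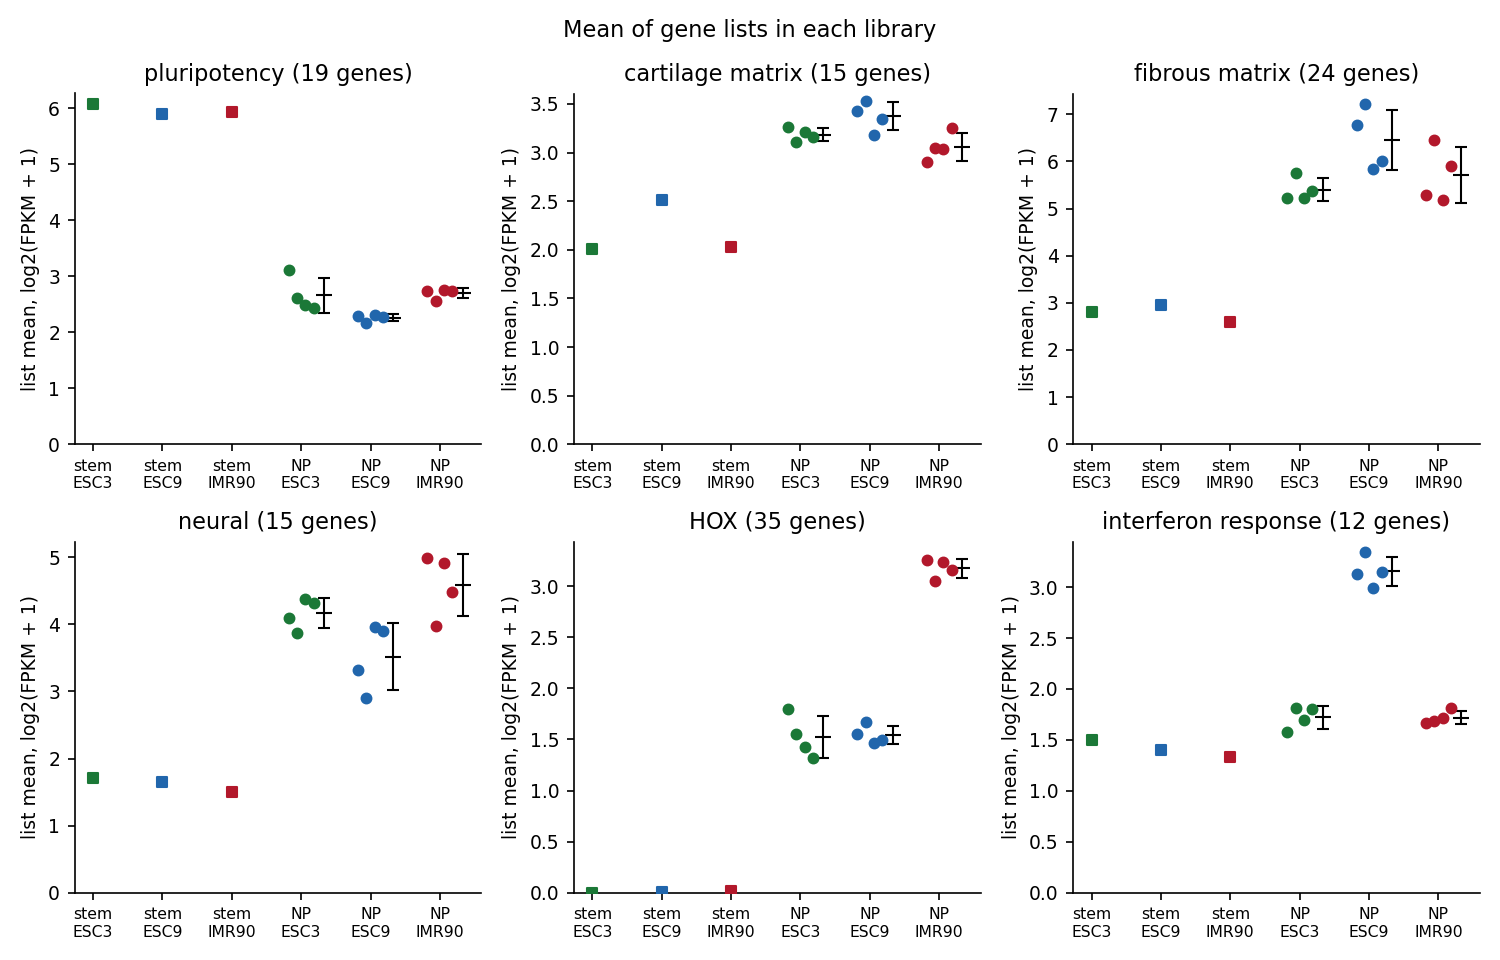
Mean log2(FPKM+1) of the tested genes of 6 lists (y axis) in each library (x axis, by line). Squares are stem libraries, circles are NP-like libraries and black bars are the mean ± SD of 4. Pluripotency genes lie at 5.90 to 6.06 in stem and 2.17 to 3.12 in NP-like libraries, HOX genes are highest in NP_IMR90, and interferon response genes are highest in NP_ESC9.

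Each line was next compared with its own stem library, to ask whether the 3 lines changed alike. Those changes shared no library between lines. In ESC3, 2020 genes were higher and 1300 lower, in ESC9 1884 and 1199, and in IMR90-iPSC 2145 and 1313. Higher in each of the 3 lines were 1080 genes and lower in each 731, of 5000 called in any line, and 13 were called in opposite directions in a pair of lines. Across genes, the log2 changes had a Pearson r of 0.858 between ESC3 and ESC9, 0.858 between ESC3 and IMR90-iPSC and 0.809 between ESC9 and IMR90-iPSC, though genes are not independent replicates. Of genes called in ESC3, 97.5% had the same sign in ESC9 and 98% in IMR90-iPSC. The lone stem library of each line was assumed to vary like the NP-like replicates. A deviation of that 1 library therefore cannot be told from a difference between lines, here or in the test of the interaction.

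The change differed among the 3 lines for 757 genes by limma's F test of the interaction, and 447 of these moved the same way in the 3 lines. Of the 757, 86 were listed at 0 in every library of at least 1 group, which leaves 671 with values above 0 in each. NANOG fell by 3.85 in ESC3, fell by 3.60 in ESC9 and fell by 1.34 in IMR90-iPSC (interaction adjusted p = 0.00226), the last of which did not pass with a pseudocount of 0.1 (-1.42, limma adjusted p = 0.129). SOST, which encodes the Wnt and BMP antagonist sclerostin, rose by 4.33, 6.35 and 2.11 in ESC3, ESC9 and IMR90-iPSC (interaction adjusted p = 0.00309). ALDH1A1, an enzyme that makes retinoic acid, rose by 3.93 in ESC3, with values of 1.07 and -0.03 in the other lines (interaction adjusted p = 0.0124). FABP7, a fatty acid binding protein of neural progenitors, rose by 3.47 in IMR90-iPSC, with values of 0.84 and -0.46 in ESC3 and ESC9 (interaction adjusted p = 0.00886). SMOC1, a secreted BMP regulator, rose by 2.81 in IMR90-iPSC, with values of 0.56 in ESC3 and -0.99 in ESC9 (interaction adjusted p = 0.00748). NTS, the neuropeptide neurotensin, had values of -1.20, -5.16 and -2.77, of which the last 2 passed (interaction adjusted p = 0.02297).

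Other genes in this set were less certain. KRT19 had values of 0.85, -0.46 and -2.99 in ESC3, ESC9 and IMR90-iPSC (interaction adjusted p = 0.0307), and did not pass without NP_ESC3 replicate 2 (interaction adjusted p = 0.0517) or NP_IMR90 replicate 1 (0.0539), 3 (0.0548) or 4 (0.0543). SERPINB9, an inhibitor of granzyme B, had values of -2.11, -0.46 and -4.41 (interaction adjusted p = 0.0376). It was lost without NP_ESC3 replicate 2 (0.0576) or 3 (0.0535), NP_ESC9 replicate 1 (0.0663), or NP_IMR90 replicate 1 (0.0666), 3 (0.0625) or 4 (0.066), and with a pseudocount of 0.1 (0.0548). TMEM132C rose by 3.42 in ESC3 and 3.95 in ESC9, but was listed at 0 in the IMR90 stem library, so no difference between lines is given for it. RNA5SP202, a pseudogene of 5S ribosomal RNA, rested on the ESC9 stem library, where it was listed at 0, against 51.7 and 73.9 FPKM in the other stem libraries. RNA5S9, a 5S ribosomal RNA gene, was listed at 0 in every library but those of NP_ESC3, which had 21.997, 7.59, 12.3 and 8.17 FPKM. These short RNAs are not polyadenylated, and their levels in polyA libraries are uncertain.

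The NP-like cells were then compared with each other, in a fit of 12 libraries. NP_ESC9 was higher than NP_ESC3 in 9 of 12 interferon response genes, 9 of 24 fibrous matrix genes and 4 of 13 imprinted genes, in lists that did not pass with an estimated correlation (adjusted p = 0.0726, 0.618 and 0.123). NNAT (ENSG00000053438.8, chromosome 20, 37521215 to 37523693), the imprinted gene neuronatin, averaged 99.6 ± 41.1 FPKM in NP_ESC9 and 0.05 ± 0.041 FPKM in NP_ESC3 (SD, n = 4 each), a log2 difference of 6.48 ± 0.24 (SE, limma adjusted p = 1.73e-09). IFIT1 (ENSG00000185745.9, chromosome 10, 89392546 to 89406486), an antiviral protein induced by interferon, averaged 14.4 ± 2.31 FPKM in NP_ESC9, 1.47 ± 0.515 in NP_ESC3 and 1.72 ± 0.208 in NP_IMR90, and was higher in NP_ESC9 than in NP_ESC3 by 2.65 ± 0.16 (limma adjusted p = 1.22e-07). Of 15694 genes tested, 323 were higher and 420 lower in NP_ESC9.

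Among the named genes of this pair, MEST, an imprinted hydrolase, averaged 362 ± 72.9 FPKM in NP_ESC9 and 31.8 ± 4.43 in NP_ESC3, a log2 difference of 3.46 ± 0.16. CHCHD2, a mitochondrial protein, averaged 67.9 ± 3.97 FPKM against 0.704 ± 0.162. IAH1, an esterase, averaged 13.4 ± 0.678 FPKM against 0.059 ± 0.025, and LINC00116 10.6 ± 1.36 FPKM against at most 0.013 in NP_ESC3. TMBIM4, a Golgi membrane protein, was listed at 0 in the 4 NP_ESC3 libraries and in the ESC3 stem library, and had 20.5, 18.8, 20.7 and 17.5 FPKM in NP_ESC9. MAGEA4, a cancer-testis antigen, had 18.997, 19.2, 16.5 and 14.5 FPKM in NP_ESC3 and was listed at 0 in NP_ESC9. NLRP2, a NOD-like receptor, averaged 17.2 ± 0.516 FPKM in NP_ESC3 and 0.082 ± 0.073 in NP_ESC9. Lower in NP_ESC9 were also the lens chaperone CRYAA (-3.52 ± 0.34), ALDH1A1 (-3.40 ± 0.31) and TMEFF2, a transmembrane proteoglycan (-3.35 ± 0.23).

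In the interferon response list, 9 of 12 tested members were higher in NP_ESC9 than in NP_ESC3, 0 lower and 3 did not pass (adjusted p = 8.35e-11, adjusted p = 0.0726 with an estimated correlation). MX1, an antiviral GTPase, was higher by 1.94 ± 0.14, IFI6 by 2.23 ± 0.12 and ISG15, a ubiquitin-like modifier, by 1.37 ± 0.17. In the fibrous matrix list, 9 of 24 were higher and 0 lower (adjusted p = 8.89e-05, adjusted p = 0.618 with an estimated correlation). DCN was higher by 3.04 ± 0.62, LUM by 2.60 ± 0.64 and POSTN, the matrix protein periostin, by 2.97 ± 0.68. NP_ESC9 replicates 1 and 2 had fibrous list means of 6.77 and 7.21 log2(FPKM+1), above the 5.85 and 6.02 of replicates 3 and 4. In the endoderm and liver list, 4 of 7 were higher and 0 lower, and 6 when adjusted over the list alone (adjusted p = 0.00303, adjusted p = 0.618 with an estimated correlation). AFP, a fetal serum protein, was higher by 2.85 ± 0.46. SERPINA1, a protease inhibitor of liver, was higher by 2.72 ± 0.34. The same NP_ESC9 replicates 1 and 2 had the highest endoderm list means, 3.14 and 4.23, and without them and NP_IMR90 replicate 2, a set chosen after seeing the data, the endoderm list did not pass (adjusted p = 0.253).

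The imprinted list had 4 of 13 members higher in NP_ESC9 than in NP_ESC3 and 0 lower (adjusted p = 0.00987, adjusted p = 0.123 with an estimated correlation). Its call was lost without NP_ESC9 replicate 1 (adjusted p = 0.079), 2 (0.182) or 4 (0.0703). PLAGL1 was higher by 1.21 ± 0.19 and PEG10 by 1.27 ± 0.16. In the smooth muscle list, 1 of 12 members was higher, DES, the muscle filament desmin, by 2.30 ± 0.26 (adjusted p = 0.0394, adjusted p = 0.618 with an estimated correlation), and the list did not pass without NP_ESC3 replicate 4 (adjusted p = 0.0724) or NP_ESC9 replicate 1 (0.0539) or 2 (0.182). In the TGF-beta list, 3 of 20 members were higher (adjusted p = 0.0394, adjusted p = 0.618 with an estimated correlation), and it did not pass without NP_ESC3 replicate 3 (0.0613) or 4 (0.0675) or NP_ESC9 replicate 1 (0.0539) or 2 (0.183). Lower in NP_ESC9 were the neural factors PAX6 (-1.73 ± 0.23) and NEUROG2 (-1.69 ± 0.26), in a neural list with 4 of 15 lower and 0 higher that did not pass (adjusted p = 0.0687). In the Wnt list, 1 of 19 members was higher and 3 lower, and the list did not pass (adjusted p = 0.0831, adjusted p = 0.618 with an estimated correlation). Among the lower were LGR5 (-2.03 ± 0.14) and SFRP2 (-2.33 ± 0.23). In the HOX list, 2 of 34 members were higher, and the list did not pass (adjusted p = 0.903). With median-ratio scaling, the smooth muscle (0.0998) and TGF-beta (0.0862) lists did not pass. Without NP_ESC9 replicates 1 and 2 and NP_IMR90 replicate 2, a set chosen after seeing the data, the smooth muscle (0.368), TGF-beta (0.513) and imprinted (0.186) lists did not pass.

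NP_IMR90 was compared with NP_ESC3, and differed in HOX genes and in S100A6. S100A6 (ENSG00000197956.9, chromosome 1, 153534599 to 153536244), a calcium-binding protein of mesenchymal cells, averaged 1.22 ± 0.298 FPKM in NP_IMR90 and 311 ± 60.2 FPKM in NP_ESC3 (SD, n = 4 each), a log2 difference of -7.12 ± 0.15 (SE, limma adjusted p = 6.89e-12). HOXA9 (ENSG00000078399.16, chromosome 7, 27162435 to 27175180), a HOX gene of posterior identity, averaged 32.5 ± 2.45 FPKM in NP_IMR90 and 4.83 ± 1.15 in NP_ESC3, a log2 difference of 2.54 ± 0.13 (limma adjusted p = 2.89e-08). In this pair, 321 genes were higher and 606 lower in NP_IMR90. In the HOX list, 27 of 34 members were higher, 0 lower and 7 did not pass (adjusted p = 2.81e-25, adjusted p = 0.0675 with an estimated correlation). HOXB9 was higher by 2.41 ± 0.26, HOXC10 by 2.22 ± 0.11 and HOXD4 by 2.34 ± 0.12. NANOG averaged 10.02 ± 0.81 FPKM in NP_IMR90 and 0.276 ± 0.388 in NP_ESC3. Without NP_ESC3 replicate 1, the NP_ESC3 mean of NANOG was 0.084 FPKM. TWIST2, a mesenchymal factor, averaged 17.5 ± 11.9 FPKM against 0.01 ± 0.011. MAF, a leucine zipper factor, averaged 0.024 ± 0.01 FPKM against 35.7 ± 6.62, and FAM19A5, a secreted brain protein, 0.011 ± 0.016 FPKM against 14.001 ± 2.095.

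Against NP_ESC3, the genes CHCHD2 (6.37 ± 0.07) and IAH1 (4.52 ± 0.06) were higher in NP_IMR90, and TMBIM4 had 18.7, 20.6, 22.2 and 22.3 FPKM. ALDH1A1 (-4.39 ± 0.31) and NLRP2 (-4.15 ± 0.08) were lower, and MAGEA4 was listed at 0 in NP_IMR90. The pseudogene SSXP10 averaged 18.8 ± 2.68 FPKM, and VTRNA2-1, a short polymerase III transcript listed at 0 in NP_ESC3, had 15.4, 14.2, 6.498 and 23.04 FPKM, both uncertain as transcripts of repeated or short genes. In the proliferation list, 1 of 23 members, the apoptosis inhibitor BIRC5, was higher (1.43 ± 0.16) and the list as a whole was higher (adjusted p = 4.90e-08, adjusted p = 0.618 with an estimated correlation). In the hypoxia and glycolysis list, 4 of 16 were lower (adjusted p = 0.00935, adjusted p = 0.515 with an estimated correlation), among them SLC2A3 (-1.60 ± 0.14). In the fibrous matrix list, 5 of 24 were higher and 2 lower, and it did not pass (adjusted p = 0.247), with DCN higher by 2.92 ± 0.62 and the elastic fiber gene ELN lower (-2.11 ± 0.26). Among keratins and galectins, KRT19 (-3.77 ± 0.36) and LGALS3 (-2.40 ± 0.15) were lower. In the TGF-beta list, 1 of 20 was higher and 5 lower, among them BAMBI (-1.88 ± 0.23), and it did not pass (adjusted p = 0.322). In the nucleus pulposus list, 4 of 23 were lower, and 6 when adjusted over the list alone (adjusted p = 0.479).

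Against NP_ESC3 the neural crest and Schwann list had 4 of 9 members higher (adjusted p = 0.0464, adjusted p = 0.618 with an estimated correlation) and did not pass without NP_ESC3 replicate 1 (adjusted p = 0.0601) or 2 (0.0851), NP_ESC9 replicate 2 (0.0504) or NP_IMR90 replicate 4 (0.0636). The epithelium list had 2 of 5 lower, CLDN4 (-3.07 ± 0.18) and KRT7 (-1.71 ± 0.42), at adjusted p = 0.0484 (adjusted p = 0.618 with an estimated correlation). It did not pass without NP_ESC3 replicate 1 (0.0501) or 2 (0.0606), NP_ESC9 replicate 1 (0.0539) or 2 (0.0582), or NP_IMR90 replicate 1 (0.0537), 3 (0.06) or 4 (0.0636). With median-ratio scaling, neither the neural crest (0.0998) nor the epithelium list (0.0556) passed, nor did the epithelium list with protein-coding genes alone (0.0526), a setting chosen after seeing the data.

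NP_IMR90 also differed from NP_ESC9, with 492 genes higher and 715 lower. Members of several lists differed, and with an estimated correlation 0 lists passed. In the HOX list, 26 of 34 members were higher and 0 lower (adjusted p = 9.68e-18, adjusted p = 0.0726 with an estimated correlation), with HOXA9 at 2.91 ± 0.13 and HOXC10 at 2.88 ± 0.11. In the interferon response list, 8 of 12 members were lower and 0 higher (adjusted p = 4.90e-08, adjusted p = 0.107 with an estimated correlation), IFIT1 at -2.49 ± 0.16. In the endoderm and liver list, 7 of 7 were lower (adjusted p = 0.00163, adjusted p = 0.618 with an estimated correlation), AFP at -4.01 ± 0.46 and SERPINA1 at -2.78 ± 0.34. In the neural list, 7 of 15 were higher and 0 lower (adjusted p = 0.00842, adjusted p = 0.618 with an estimated correlation), among them SOX1 (3.08 ± 0.35) and DCX, a microtubule protein of young neurons (2.39 ± 0.36). Neural list means were 3.32 and 2.90 in NP_ESC9 replicates 1 and 2, 3.96 and 3.90 in replicates 3 and 4, and 3.98 to 4.985 in NP_IMR90. NP_ESC9 replicates 1 and 2 also had the highest fibrous list means of the NP-like libraries. In the neural crest and Schwann list, 3 of 9 were higher (adjusted p = 0.00917, adjusted p = 0.618 with an estimated correlation). In the list for matrix turnover and cytokines, 6 of 8 were lower (adjusted p = 0.00403, adjusted p = 0.618 with an estimated correlation), among them CCL2 (-1.38 ± 0.15).

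Against NP_ESC9, S100A6 (179 FPKM there) had a log2 difference of -6.34 ± 0.15, MAF of -5.15 ± 0.14 and NNAT of -6.49 ± 0.24. TMEM132C (-4.36 ± 0.13) and SOST (-4.17 ± 0.25) were also lower. Higher were NANOG (3.43 ± 0.16), LCN9, a lipocalin (3.89 ± 0.11), C1orf61 (3.61 ± 0.65) and PENK, the precursor of enkephalins (3.53 ± 0.41). SSXP10 was higher as well (3.91 ± 0.12), and CYP4F29P, a cytochrome pseudogene listed at 0 in NP_ESC9, had 10.03, 9.57, 9.795 and 10.6 FPKM. In the TGF-beta list, 1 of 20 members was higher and 6 lower (adjusted p = 0.00624, adjusted p = 0.618 with an estimated correlation). In the hypoxia and glycolysis list, 2 of 16 were lower (adjusted p = 0.00367, adjusted p = 0.439 with an estimated correlation), and the proliferation list was higher with 0 of 23 members passing singly (adjusted p = 0.000177, adjusted p = 0.618 with an estimated correlation).

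In this pair 3 list calls hung on single libraries. In the fibrous matrix list, 1 of 24 members was higher and 8 lower in NP_IMR90 (adjusted p = 0.0443, adjusted p = 0.759 with an estimated correlation), a call lost without NP_ESC9 replicate 1 (adjusted p = 0.063) or 2 (0.29) or NP_IMR90 replicate 1 (0.0983) or 3 (0.135). In the imprinted list, 1 of 13 was lower (adjusted p = 0.00941, adjusted p = 0.123 with an estimated correlation), lost without NP_ESC9 replicate 1 (0.0539) or 2 (0.074). In the pluripotency list, 3 of 14 were higher and 1 lower (adjusted p = 0.0227, adjusted p = 0.545 with an estimated correlation), lost without NP_IMR90 replicate 1 (0.0753), 3 (0.0667) or 4 (0.0648). The fibrous matrix list also did not pass with median-ratio scaling (0.0723). In settings chosen after seeing the data, it did not pass with protein-coding genes alone (0.0546) or without NP_ESC9 replicates 1 and 2 and NP_IMR90 replicate 2 (0.121), nor did the imprinted list without those 3 libraries (0.0633).

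The iPSC-derived cells were last set against the mean of the ESC-derived NP-like groups, which asks about the source of the cells, though with 1 iPSC line the source and the line cannot be separated. In NP_IMR90, 326 genes were higher and 565 lower. S100A6 had a log2 difference of -6.73 ± 0.13 (limma adjusted p = 3.60e-12) and MAF of -5.15 ± 0.12, and NANOG was higher by 3.29 ± 0.14. Every HOX cluster held higher genes, among them HOXA9 (2.72 ± 0.11), HOXB9 (2.80 ± 0.22), HOXC10 (2.55 ± 0.10) and HOXD4 (2.56 ± 0.10). LCN9 (3.85 ± 0.10), CHCHD2 (3.70 ± 0.06) and TWIST2 (3.56 ± 0.29) were higher too. The CHCHD2 difference came mostly from its low level in NP_ESC3, since NP_ESC9 expressed it as well. SLC15A4, a lysosomal transporter, was listed at 0 in the 4 NP_IMR90 libraries, against 11.7 ± 0.79 FPKM in NP_ESC3 and 15.3 ± 0.688 in NP_ESC9. TMEM132C (-4.03 ± 0.11), FAM19A5 (-3.69 ± 0.10) and the protocadherin PCDHB5 (-3.38 ± 0.06) were lower. KRT19 (-3.18 ± 0.31) and COL14A1 (1.76 ± 0.10) differed in opposite directions.

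**Figure D3:**
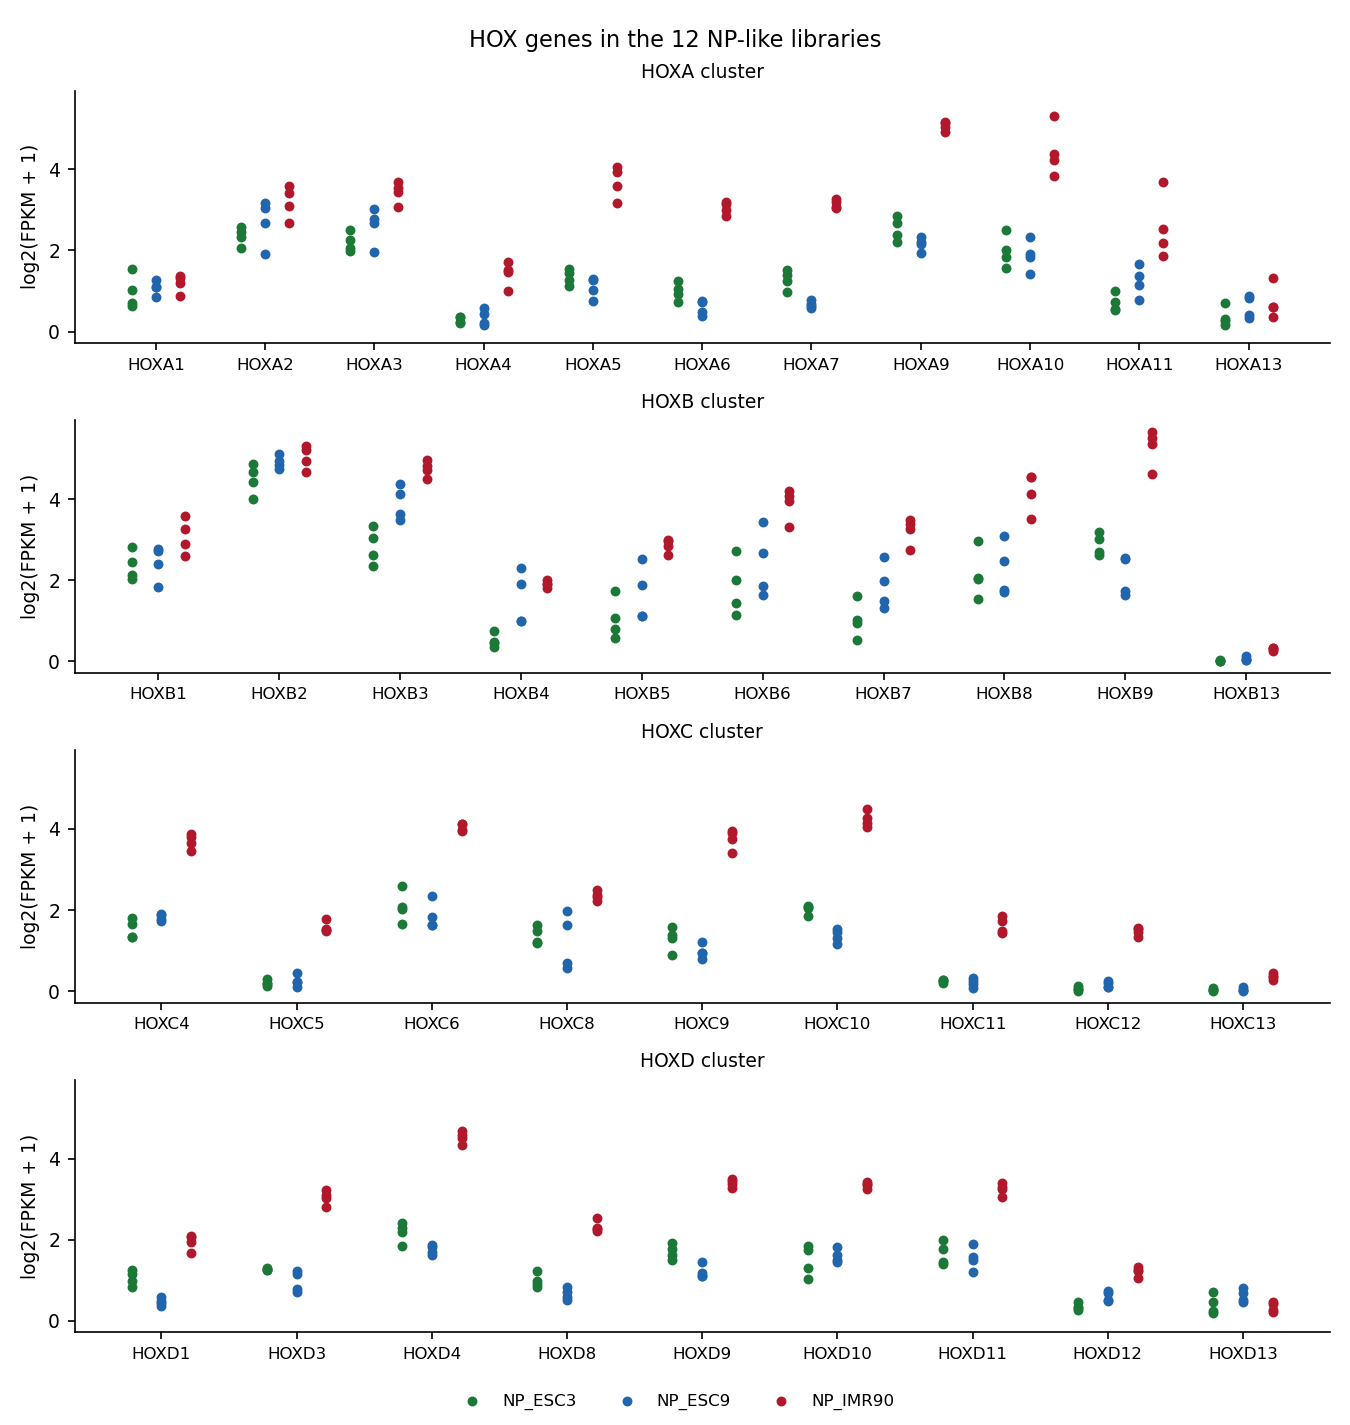
Log2(FPKM+1) (y axis) of 39 HOX genes by cluster (x axis) in the 12 NP-like libraries. Points are libraries, colored by line. HOXA9 averages 32.5 FPKM in NP_IMR90 against 4.83 in NP_ESC3 and 3.48 in NP_ESC9.

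Over the 3 pairs of NP-like groups, 23 of 69 list tests were called with the preset correlation and 0 with an estimated correlation. The median, the mean and the test differed in sign for 5 lists in NP_ESC9 versus NP_ESC3, 5 in NP_IMR90 versus NP_ESC3 and 1 in NP_IMR90 versus NP_ESC9, and 0 of these were called.

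Among NP-like libraries of the same line, fibrous matrix and neural genes differed in opposite directions. With each library taken relative to the mean of its line, the fibrous and neural list means had a Pearson r of -0.972 (permutation p = 0.00101, adjusted p = 0.00203) and a Spearman rho of -0.951 (permutation p = 0.0013) over 12 libraries, and r was -0.936 without the 2 farthest libraries. Smooth muscle genes moved with fibrous genes (r 0.979, permutation p = 0.00094, adjusted p = 0.00203, rho 0.951, permutation p = 0.000506, r 0.966 without the 2 farthest). Endoderm genes did so less tightly (r 0.769, permutation p = 0.000579, adjusted p = 0.00203, rho 0.818, permutation p = 0.00658, r 0.751 without the 2 farthest). Neural crest genes moved with neural genes by Pearson r (0.759, permutation p = 0.0248, adjusted p = 0.0331, 0.66 without the 2 farthest) but not by Spearman rho (0.713, permutation p = 0.0809). Proliferation genes did not pass against fibrous genes (r -0.618, permutation p = 0.066, adjusted p = 0.0754, rho -0.545, permutation p = 0.121), and that r was -0.259 without the 2 farthest. Adjusted p-values cover a family of 8 relations, with libraries rearranged within lines in 13824 ways. The libraries with the highest fibrous list means were NP_ESC9 replicates 2 (7.21) and 1 (6.77) and NP_IMR90 replicate 2 (6.46), with neural means of 2.90, 3.32 and 3.98. Replicate 2 had the highest fibrous and the lowest neural mean of its group in each line, NP_ESC3 replicate 2 at 5.75 and 3.88. Those p-values take the lines as independent, and they are too small if a replicate number marks a shared culture or batch, which the labels do not say. With the replicate numbers rearranged alike in the 3 lines, a test chosen after seeing the data, the permutation p of the fibrous and neural relation was 0.0417, the smallest that 24 arrangements can give, and its adjusted p of 0.0556 over 8 relations did not pass. The relations of fibrous with smooth muscle genes and with endoderm genes had the same permutation p and adjusted p, and did not pass either. With the means of both line and replicate number taken out, r was -0.921 for fibrous and neural genes and 0.949 for fibrous and smooth muscle genes. It was 0.518 for fibrous and endoderm genes, and 0.346 to 0.769 without each library in turn. For neural and neural crest genes it was 0.59, and their permutation p with numbers rearranged alike was 0.125.

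**Figure D4:**
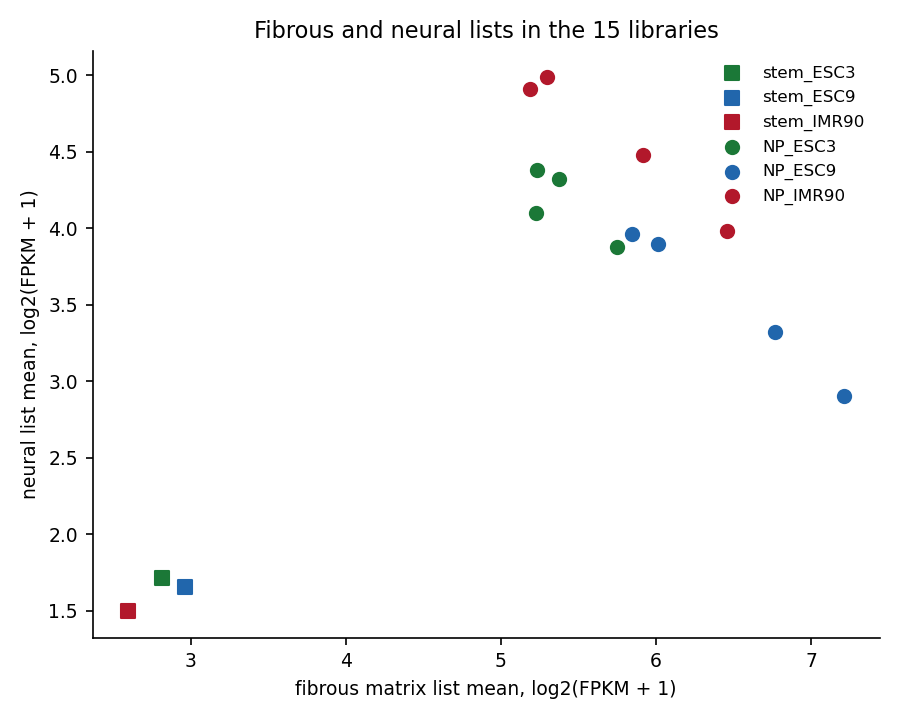
Mean log2(FPKM+1) of 24 fibrous matrix genes (x axis) against that of 15 neural genes (y axis) in 15 libraries. Squares are stem libraries and circles are NP-like libraries, colored by line. NP_ESC9 replicate 2 has the highest fibrous mean (7.21) and the lowest neural mean (2.90) of the NP-like libraries.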

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

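The tests of the cell shares, of the 3 explanations for NANOG and of HOX transcripts in stem cells were chosen only after the result was seen, as were the depth-adjusted relation and the tests of replicate numbers, and the others were written before. The search for libraries far from their group was widened after the data were seen, to every named gene.

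Among 219 groups of 4 libraries, 7 held a library far from the others, measured as log2(FPKM+1), and chance alone gives about 1 in 20 such groups, so 7 is no more than chance gives. WLS was at 7.744 in NP_ESC9 replicate 2, against 8.156 to 8.169 in the others. LECT1 was at 1.679 in NP_ESC3 replicate 1, against 0.676 to 0.747, and SOST at 3.83 in the same library, against 4.72 to 4.894. CHCHD2 was at 7.028 in NP_IMR90 replicate 2, against 7.16 to 7.17. NLRP2 was at 4.246 in NP_ESC3 replicate 4, against 4.161 to 4.171. VTRNA2-1 was at 2.984 in NP_ESC9 replicate 2 and listed at 0 in the others. The pluripotency list mean was 2.556 in NP_IMR90 replicate 2, against 2.73 to 2.761.

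The change from stem to NP-like cells differed among the 3 lines for 757 genes by limma's interaction test. With 1 stem library per line, assumed to vary like the NP-like replicates, a deviation of that library cannot be told from a difference between lines. The range over the lines of the log2 change was 4.25 for SOST, 3.96 for ALDH1A1, 3.96 for NTS, 3.95 for SERPINB9, 3.92 for FABP7, 3.84 for KRT19 and 3.8 for SMOC1. Among the other named genes it was 3.57 for S100A6, 3.56 for CRYAA, 3.55 for TMEFF2, 3.53 for CHCHD2, 3.2 for MEST, 2.97 for TWIST2, 2.5 for NANOG, 1.79 for SEMA3C, 1.43 for LCN9, 1.42 for IAH1 and 1.28 for WLS. Of the 757 genes, 86 were listed at 0 in every library of at least 1 group, which may be estimates that were not made. RNA5SP202, TMEM132C, RNA5S9, SSXP10 and MAF are of that kind, with a stem library listed at 0, so no range is given for them. PCDHB5 passed the interaction test with a range of 0.89, under the minimum of 1.

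Other splits of the samples were counted for each comparison. For NP-like versus stem cells, 10 splits are too few for a share under 0.05, with 3077 genes in the real split and at most 0 in the others, and 16 lists against at most 15, so that the real split alone, 1 of 10, gave as many. Between NP-like groups the real grouping alone gave the highest counts of genes. These were 743 for NP_ESC9 versus NP_ESC3 (at most 1 in the others of 35 splits) and 927 for NP_IMR90 versus NP_ESC3 (at most 1). They were 1207 for NP_IMR90 versus NP_ESC9 (at most 2) and 891 for NP_IMR90 versus the mean of the ESC-derived groups (at most 32 in 100 assignments). So the libraries differed more between groups than an arbitrary grouping gives. Such splits take libraries as independent and ignore replicate numbers. They cannot exclude a chance difference between single cultures, batches or lines. Chance cannot be excluded for the number of lists called between NP-like groups, 23 in the real assignment and up to 42 in the others, with 58 of 100 assignments giving as many. The counts of members per list do not rest on this number.

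Fibrous matrix and neural list means differed in opposite directions among NP-like libraries of a line. Abundant matrix transcripts that lower all other FPKM values would be removed by median-ratio scaling, after which r was -0.956 (permutation p = 0.0013). Depth had an r of -0.424 with the fibrous mean (permutation p = 0.248), which alone leaves it open. The relation with the estimated depth taken out kept an r of -0.971 (permutation p = 0.000868). That argues against depth, as far as an estimate from few genes per library can. Replicate 2 had the highest fibrous and lowest neural mean in each of the 3 lines, so a shift shared by a replicate number was tested: with the means of line and number taken out, r was -0.921, and -0.89 to -0.991 without each library in turn, which argues against such a shift as the whole cause. A part shared by the number stays open, and the permutation p-values here take the lines as independent. With numbers rearranged alike in the 3 lines, the relation after scaling and that with depth taken out each had a permutation p = 0.0417, the smallest that 24 arrangements can give, and an adjusted p of 0.0556. Different shares of fibroblast-like and neural cells in the cultures stay open. Smooth muscle genes moved with fibrous genes (r 0.979, and 0.928 to 0.968 with number means taken out, without each library in turn). The link of neural crest to neural genes is weaker: r was 0.759, its rho did not pass (permutation p = 0.0809), numbers rearranged alike gave a permutation p = 0.125 (adjusted p = 0.143), and with number means taken out r was 0.59, and 0.336 to 0.765 without each library in turn. Bulk RNA also cannot separate cell shares from changes within cells.

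NANOG was at 10.0 FPKM in NP_IMR90, 37.2% of the IMR90 stem level, while POU5F1 was at 0.116 FPKM, 0.0299% of its IMR90 stem level. Remaining pluripotent cells would bring their other transcripts in the same share. The median kept by 13 other pluripotency genes was 4.9%, with shares from 0.00783% to 45.5%, and 1 of the 13 kept more than NANOG. The 13 were chosen among genes called lower in NP-like cells, which favours a low median. GDF3, which also kept more than NANOG, was left out of them. Reads of the retrocopy NANOGP8 cannot be told apart from NANOG: their mean ratio was 0.168 in NP_IMR90, and 0.13 to 0.253 by library overlaps the 0.18 to 0.35 of stem libraries. A NANOG locus that stays active is left open, since 1 of 2 neighbours on chromosome 12 was higher in each NP_IMR90 library than in every ESC-derived one. GDF3 was, at 0.744 FPKM or more against at most 0.233, and kept 45.6% of its IMR90 stem level. NANOGP1 was not, at 0.058 to 1.223 FPKM against at most 0.125, and kept 7.52%. A NANOG copy inserted by reprogramming stays open, since the labels name no vector.

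HOX genes were higher in NP_IMR90 than in the ESC-derived NP-like cells, by 1.64 in the list mean. Adjusted for the fibrous and neural list means, the difference was 2.25 ± 0.22 (SE, 7 residual degrees of freedom), which argues against different amounts of fibrous and neural transcripts as the cause. The adjustment rests on slopes within lines, where the 2 list means were closely tied (r -0.972). The list means do not measure which kinds of fibrous or neural cells are present, so that part of the makeup stays open. Transcripts already present in the IMR90 stem cells are argued against for the 17 HOX genes with a value above 0 there, of which 0 reached 1 FPKM and the highest was 0.067; 15 of them were called higher in NP_IMR90 than in the mean of the ESC-derived groups. For the other 22, listed at 0 there, of which 13 were called higher, this stays open, since a listed 0 may be an estimate that was not made. Whether the line, its source or the timing of its differentiation accounts for the difference is untested, since there is 1 iPSC line.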

How the results depend on the processing

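Protein-coding genes alone, the libraries with high fibrous list means left out and the single-library leave-outs of lists and agreement were chosen after seeing the data. Among the named or listed genes that were checked, no called gene reversed under any alternative run. Of 226 such genes called in NP-like versus stem cells, 163 kept the call under every alternative in which they were tested. A gene left out by the filter or gene type of an alternative was not tested there and does not count as lost. Called genes that were neither named nor listed were checked only for calls kept in the same direction. Without a fold minimum, the counts were 7790 for NP-like versus stem cells, 8349, 7948 and 8494 within ESC3, ESC9 and IMR90-iPSC, 1138 for the interaction, and 6040, 6062, 6872 and 6793 for NP_ESC9 versus NP_ESC3, NP_IMR90 versus NP_ESC3, NP_IMR90 versus NP_ESC9 and NP_IMR90 versus the mean of the ESC-derived groups. That follows from dropping the minimum. With a filter of 5 FPKM, which tests fewer genes, the interaction gave 469 and those 4 comparisons 424, 549, 732 and 545. With a pseudocount of 0.1, which widens differences at low values, they gave 1347, 1524, 1919 and 1456. With an estimated correlation, 0 lists passed in NP-like versus stem cells and 0 between NP-like groups. That test also has fewer degrees of freedom, 2 and 9, so the loss does not show by itself that correlated genes made the calls. The cause was not tested. Leaving out single NP-like libraries, and for NP-like versus stem cells also single lines, gave 2434 (without the ESC3 line) to 3107 genes for that comparison, 3269 to 3355, 3010 to 3118 and 3398 to 3498 within lines, 606 to 914 for the interaction, 649 to 757, 837 to 969, 1036 to 1272 and 758 to 932 between NP-like groups, 14 to 16 and 17 to 28 lists, and a mean agreement of 0.833 to 0.847. Without the 3 libraries with high fibrous list means there were 3114 genes for NP-like versus stem cells and 663, 972, 941 and 778 between groups, and with protein-coding genes alone 2700 and 597, 768, 1012 and 748. Median-ratio scaling moved the median gene change from 0.098 to 0.027. Depth limits genes under 1 FPKM, such as T, NOTO and PAX1.

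The replicate number as a block gave 769, 956, 1228 and 898 genes between NP-like groups and 30 lists. The block was not used, since not every pair of libraries that share a number had a correlation of deviations from the group mean over 0.1: 9 of 12 pairs did, from -0.281 to 0.642, with a mean of 0.214 against -0.068 for other numbers. In 10 of 24 comparisons with another line a library was closest to its own number, and 2 of 12 libraries were so in both other lines. A batch shared by some numbers stays possible as a hint from the data, since the labels name none.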

Other observations

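The tests of line differences in stem libraries were chosen only after the result was seen. Differences between the NP-like groups were in part present in the stem libraries, which share no library with them. Of 743 genes that differed between NP_ESC9 and NP_ESC3, 558 (75.1%) had the same sign between the stem libraries, and 206 (27.7%) differed there at least 2-fold the same way, against 2.1% of the other genes that differed 2-fold in either direction. For NP_IMR90 versus NP_ESC3 these were 668 of 927 (72.1%) and 220 (23.7%), against 1.9%, and for NP_IMR90 versus NP_ESC9 809 of 1207 (67%) and 232 (19.2%), against 2.2%. With 1 stem library per line these are values with no test.

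Named genes of that kind were CHCHD2, at 11.98, 44.6 and 117 FPKM in the ESC3, ESC9 and IMR90 stem libraries, and IAH1, an esterase, at 0.085, 4.502 and 11.3. NLRP2 was at 36.3, 0.463 and 0.942 and NNAT at 0.054, 27.3 and 0.06. SLC15A4 was at 9.82, 13.4 and 0.012. FAM19A5 was at 13.4 and 15.9 and listed at 0 in IMR90, and TMBIM4 was listed at 0 in ESC3 and at 21.8 and 14.8 in the other lines. IFIT1, which differed between NP-like groups, varied little among stem libraries, at 1.06, 1.25 and 1.38 FPKM.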
